A study of Homo sapiens with 2 samples.

How the data were processed

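RNA sequencing of 2 libraries of MCF7 cells was analysed, 1 from cells carrying a control vector and 1 from cells overexpressing miR25/93. MCF7 is an established luminal breast cancer cell line of epithelial type. Per the labels' protocols, the cells were cultured in DMEM without further treatment, RNA was extracted with Trizol, and libraries were made with standard Illumina methods. The groups were taken from the labels, with 1 library per group. There were no replicates, so no difference has a replicate check, no test between conditions was run and no p-value is given.

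The values are FPKM (fragments per kilobase of transcript, scaled to the fragments in the library) as the authors deposited them, in 1 table of 26457 RefSeq transcript rows with 3 decimals. The submitters' processing notes name the genome build hg19 and the tools STAR and HOMER, without versions, roles or order. The unit was read from the table's name, and the values do not contradict it. Whether strand was used in counting is not given in the sources used here, so reads from a gene and an overlapping antisense gene cannot be told apart. Gene symbols, gene types and chromosome bands are those of the table. The 1 symbol on more than 1 row was represented by its row with the highest mean, which left 26456 genes.

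The sequencing depth is not stated. Low FPKM values multiplied by transcript length fell on regular steps, the lowest of which was taken as 1 read. Transcript lengths came from GENCODE 29, matched through RefSeq accessions for 24694 genes (93.3%). The steps gave an estimate of 26600000 reads for the control and 29000000 for the miR25/93 library, a ratio of 1.091. The low genes alone, without lengths, gave a ratio of 0.915 for the FPKM worth of 1 read. Estimated read numbers gave the 95% counting intervals of single-gene ratios, for genes with a known length and at least 3 reads in each library. These intervals cover counting error only, not variation between cultures.

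The measure was the difference in log2(FPKM + 1), miR25/93 minus control. This scale understates the change of genes with low values. Genes with FPKM of at least 1 in at least 1 library were analysed, and a gene was called higher or lower at a difference of at least 1 in size, 2-fold on that scale. Percent of control and fold values of single genes are plain ratios of FPKM without the added 1. For each gene list, the median difference was placed among the medians of 10000 random lists with the same number of genes in each of 20 bins of mean expression. The percentile describes these 2 libraries, and the marks were 2.5 and 97.5. Lists with fewer than 3 measured genes got no percentile.

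Seed sites were searched in the 3' UTR of the longest protein-coding transcript of each gene in GENCODE 29. That annotation belongs to GRCh38, another build than the table's, so it gave sequences and lengths but no coordinates. A site was a match to bases 2 to 8 of miR-25-3p or miR-93-5p. Random lists for the site genes were matched on expression and on 10 bins of UTR length. Each site word was also ranked among all words of 7 bases with the same base composition that occurred in at least 50 genes. UTRs were first matched by gene symbol alone, which covered 12016 genes (96.7% of the protein-coding genes analysed) and missed MB21D1. After that result had been seen, matching through the RefSeq accession was added, which covered 12326 genes (99.2%). Both versions are reported.

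The measure, the 27 gene lists and the rule for naming genes were fixed before the data were examined. The rule names all study genes and miRNA genes, the 12 largest differences in each direction among genes with FPKM of at least 5 in at least 1 library (small RNA genes left out), and up to 4 measured members of each other list with the largest differences. A further 5 lists were written after the values of the fixed lists had been seen: genes lost in MCF-7, genes in segments amplified in MCF-7, and markers of an embryonic kidney line, of fibroblasts and of basal breast lines. CDKN2A, COL1A2, KRT5 and KRT14 had been seen when these were written. Other genes named from the fixed lists serve as examples and were chosen after their values were seen.

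The statistics were tested on simulated libraries drawn from the control values. These libraries held counting noise only, not variation between cultures. They also lacked broad differences like those of the real pair, with 1911 genes higher and 676 lower. The no-change values for seed sites below therefore do not calibrate the percentile and word ranks of the real libraries. The recovered depth was off by 0.00665% for the control and 0.0479% for the miR25/93 library, over 24694 genes. Drawing and recovery used the same transcript lengths, so errors in those lengths were not tested. Of 50 genes per fold size, 96% of those set to 0.25 of control, 66% of those at 0.4, 92% of those at 2.5 and 100% of those at 4 were called. Counting noise called 62 of 11866 unchanged genes. A list of 20 genes at 0.7 of control came out at percentile 0, and 2 of 40 lists of unchanged genes fell outside the marks. With the site genes at 0.95 of control their percentile was 0, and with no change it was 29.4. The share of words as low as the miR-25-3p and miR-93-5p words was 0.159% and 0.238% with the site genes at 0.95 of control, and 49.8% and 27.4% with no change.

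The alternatives were pseudocounts of 0.1 and 5, other filters on low values, rescaling to the same median or 75th percentile, summed rows, small RNA genes left out, 10 expression bins, 8-base sites and sites in any annotated 3' UTR. Counting lower genes from the epithelial list's median, matching UTRs by symbol alone and applying the 75th percentile rescaling to lists were added after the data had been seen. Rescaling to the same median shifted the miR25/93 library by -0.004 on the log2 scale, and rescaling to the same 75th percentile by 0.06. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.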

Results

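RNA was sequenced from MCF7 cells, a luminal breast cancer line, carrying either a control vector or overexpressing miR25/93, with 1 library per condition. The series set out to find genes downstream of these microRNAs, and what is known of the study adds a question about the DNA sensor cGAS and the coactivator NCOA3. FPKM values were above 0 for 18441 genes in the control and 20004 in the miR25/93 library, and at least 1 for 12455 and 13667 genes. The estimated depths were 26600000 and 29000000 reads. Neither condition was replicated, so each difference below compares 2 libraries and has no replicate check. Intervals in parentheses are 95% counting intervals and cover counting error only.

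The microRNA genes themselves were higher in the library labelled miR25/93. MIR25 (7q22.1) was at 12.2 FPKM in the control and 42.5 in the miR25/93 library, 3.49-fold higher (2.29 to 5.33). MIR93, in the same cluster, was at 3.32 and 19.5 FPKM, 5.88-fold higher (2.66 to 13.004), from an estimated 7 reads in the control. MIR106B, the remaining member of the cluster, was at 1.39 and 2.96 FPKM with an interval that included no difference. MCM7, the helicase gene whose intron holds the cluster, was at 196 and 134 FPKM, 68.5% of control (66.9 to 70.2). These values come from gene rows of an RNA library and do not measure the mature microRNAs.

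MB21D1 and NCOA3 were both lower with miR25/93. MB21D1 (6q13), which encodes cGAS, was at 9.60 FPKM in the control and 2.52 in the miR25/93 library, 26.3% of control (22.7 to 30.4). NCOA3 (20q12), which encodes a steroid receptor coactivator, was at 203 and 74.0 FPKM, 36.5% of control (35.7 to 37.4). Among the 8614 genes with at least 5 FPKM in the control, 0.789% had a percent of control as low as MB21D1 and 3.03% as low as NCOA3. In the same library the median of the epithelial list was 38.6% of control, with an interquartile range of 35.3 to 49.2% and a 5th percentile of 29.02%. The median of genes in segments amplified in MCF-7, a list that excludes NCOA3, was 39.9%. TMEM173, which encodes STING, the adaptor downstream of cGAS, went the other way, from 0.676 to 10.7 FPKM, 15.8-fold (9.59 to 26.1). It was 1 of 102 genes under 1 FPKM in the control and at 10 or more with miR25/93, against 1 gene in reverse. Whether RNA of other cells, weighed at the end, raised TMEM173 was not tested. Of the TET enzymes, which oxidise methylated cytosine, TET1 was higher at 0.368 and 2.68 FPKM, TET2 was lower at 20.9 and 7.47 FPKM (35.7% of control), and TET3 was at 15.6 and 10.7 FPKM without a call. With a pseudocount of 5 the differences of MB21D1 (-0.96) and TET1 (0.52) were short of the call.

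Across 14077 genes, 1911 (13.6%) were higher and 676 (4.80%) lower by at least 2-fold with miR25/93, and 11490 were neither. Of the called genes 73.9% were higher. This split depended on genes with low control values: with FPKM of at least 1 in both libraries, 836 genes were higher and 581 lower, and 59.0% of called genes were higher. The counts depended on the pseudocount too, with 552 higher and 262 lower at 5, and 2589 and 1031 at 0.1. The median difference over the 14077 genes was 0.11, and it was 0.11 after rescaling to the same median and 0.16 after rescaling to the same 75th percentile. Over the 8021 genes at 5 FPKM or more in both libraries the median log2 ratio was 0.004. Genes that were near silent in the control and abundant in the other library occurred in 1 direction: 42 genes were under 0.1 FPKM in the control and at 10 or more with miR25/93, and 0 were the reverse. Of the 6067 genes at 10 FPKM or more in the control, 11 were under 20% of control.

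**Figure D1:**
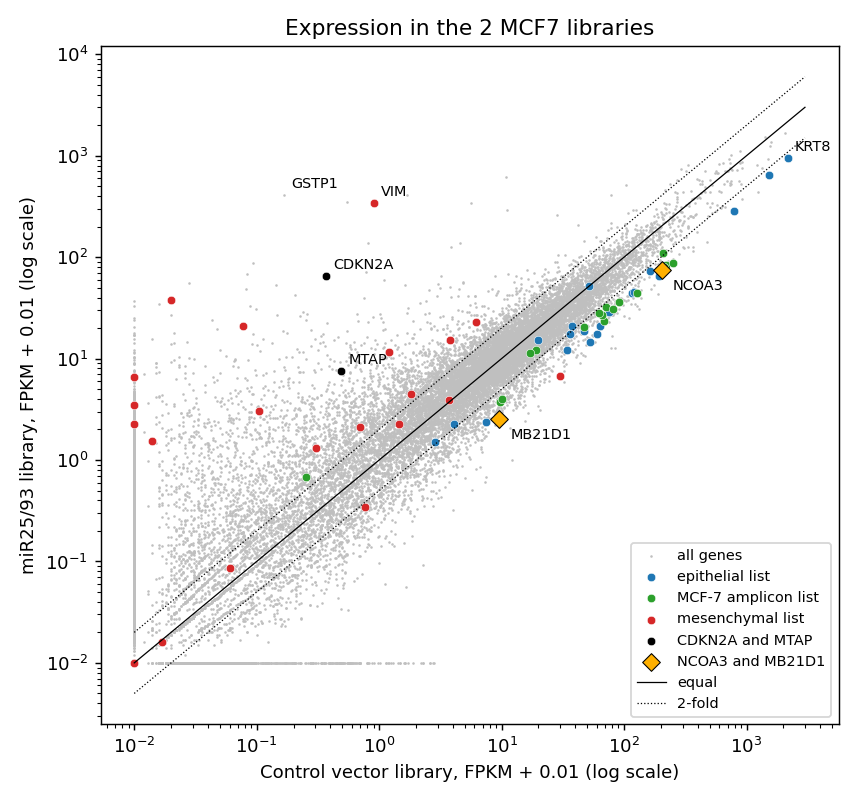
FPKM of each gene in the control library (x axis) against the miR25/93 library (y axis), both plus 0.01 on log scales, with 1 grey point per gene and genes of the named lists in colour; X inactivation and Y chromosome genes are not drawn. Epithelial and amplicon genes lie mostly below the lower 2-fold line, at medians of 38.6% and 39.9% of control, NCOA3 lies among them at 36.5%, MB21D1 lies at 26.3%, and genes such as GSTP1, VIM and CDKN2A lie far above the upper line.

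The 12 largest higher differences included 9 genes under 1 FPKM in the control, with PLS3, CKB and LDHB above that. GSTP1, a glutathione transferase, was at 0.158 FPKM in the control and 406 with miR25/93. UCHL1, a neuronal ubiquitin hydrolase, was at 0.538 and 348 FPKM, and the intermediate filament gene VIM at 0.899 and 342. VIM-AS1, which overlaps VIM, was at 0.8 and 138 FPKM, and the 2 cannot be separated without strand. The actin regulators PLS3 (1.69 and 410 FPKM), CNN3 (0.018 and 56.2) and MSN (0.133 and 53.2) followed the same direction. So did the metabolic enzymes LDHB (10.9 and 615 FPKM) and CKB (5.64 and 338), the peroxidase GPX1 (0.083 and 87.7) and C10orf10 (0.073 and 67.8). CDKN2A (9p21), the cell cycle inhibitor gene, was at 0.359 and 64.7 FPKM. Its neighbour MTAP (9p21), an enzyme of methionine salvage, was at 0.480 and 7.52 FPKM, 15.7-fold (12.1 to 20.2). MCF-7 is known to have lost the segment that holds both genes.

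The 12 largest lower differences ran from -2.86 for CEACAM6 to -2.17 for SHH. The adhesion molecule genes CEACAM6 (19.6 and 1.84 FPKM, 9.37% of control) and CEACAM5 (16.5 and 1.64 FPKM, 9.93%) were lowest by this measure. The kinesin KIF12 was at 12.04 and 0.984 FPKM (8.18%), the amino acid transporter SLC6A14 at 84.3 and 12.6 (14.9%), the Rac exchange factor PREX1 at 78.9 and 12.7 (16.1%), and the calcitonin receptor CALCR at 20.6 and 3.13 (15.2%). The others were CT83, DIO2, CDH26, LINC01468, CALML5 and the signalling ligand SHH, between 8.17 and 21.3% of control. Counted on the log2(FPKM + 1) scale from the median difference of the epithelial list, and not from 0, 8 genes were lower by 2-fold. They were CEACAM6, CEACAM5, KIF12, SLC6A14, PREX1, CALCR, CT83 and DIO2. That scale leaves out genes as low by plain percent of control, such as CDH26 (15.6%) and AREG (14.1%) beside PREX1 (16.1%).

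Epithelial and estrogen response genes were lower and mesenchymal genes higher in the miR25/93 library. As weighed at the end, MTAP argues against a change within MCF-7 cells alone, and RNA from other cells is a candidate explanation. These list differences therefore do not show that the MCF-7 cells changed state. Of 20 measured epithelial genes 15 were lower and 0 higher, with a median difference of -1.32, at percentile 0 of random lists. CDH1 (E-cadherin) was at 193 and 65.4 FPKM (33.8% of control), the splicing factor ESRP1 at 60.1 and 17.5 (29.1%), the GTPase RAB25 at 63.7 and 20.8 (32.6%) and the protease ST14 at 52.7 and 14.7 (27.9%). The desmosome gene DSP was an exception at 51.4 and 52.3 FPKM. Of 29 measured estrogen response genes 17 were lower and 0 higher (median -1.16, percentile 0). The estrogen receptor gene ESR1 was at 57.4 and 16.98 FPKM (29.6%), IGFBP4 at 174 and 53.4 (30.7%), STC2 at 88.0 and 28.4 (32.3%) and PKIB at 33.4 and 8.79 (26.3%). Of 16 measured genes in segments amplified in MCF-7, 13 were lower and 0 higher (median -1.22, percentile 0), among them RPS6KB1 (35.2%), BCAS3 (38.2%) and ZNF217 (38.3%). Of 17 measured mesenchymal genes 11 were higher and 1 lower (median 1.74, percentile 100). The size of this median depended on low values: it was 0.66 with a pseudocount of 5, 3.19 with a pseudocount of 0.1 and 2.73 with FPKM of at least 5, each at percentile 100. The matrix protein SPARC was at 0.010 and 37.8 FPKM, N-cadherin (CDH2) at 0.068 and 20.8, and the transcription factor TWIST1 was listed at 0 in the control and at 6.64. TGFBI was the lower member, at 29.8 and 6.79 FPKM. Of 12 basal epithelial genes 2 were higher (CD44, EGFR) and 2 lower (ITGB4, CAV1), with a median of -0.32 at percentile 1.38 that changed sign with FPKM of at least 5 and with no filter. With a pseudocount of 5 this list was within the random range and CD44, EGFR and CAV1 lost their calls, as did BCAS1 and EYA2 of the amplicon list.

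**Figure D2:**
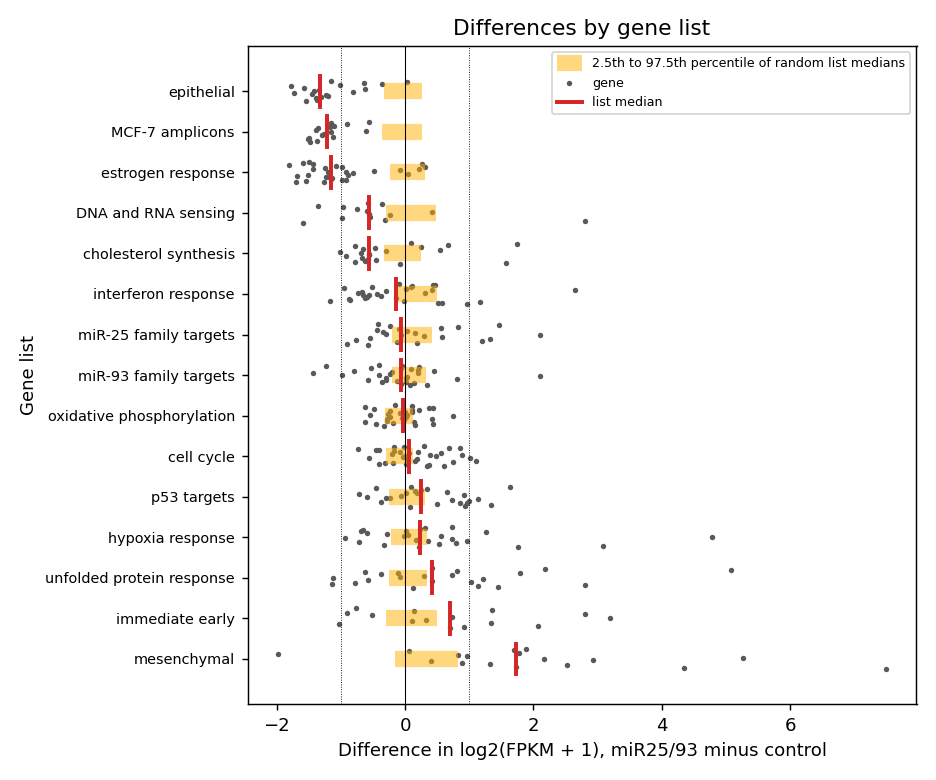
Difference in log2(FPKM + 1), miR25/93 minus control (x axis), for the measured genes of 15 lists (y axis). Grey points are genes, red bars list medians, and yellow bars the central 95% of random list medians; dotted lines mark 2-fold. The epithelial, amplicon and estrogen response medians (-1.32, -1.22 and -1.16) lie left of their random ranges and the mesenchymal median (1.74) lies right of its range.

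The median of nucleic acid sensing genes lay below that of random lists, and single genes of this and the interferon list went both ways. Of 14 measured sensing genes 2 were lower and 1 higher, with a median of -0.57 at percentile 0.01. Beside MB21D1 the adaptor MYD88 was lower, at 17.7 and 6.26 FPKM (35.4% of control), the kinase gene IKBKE was at 4.76 and 1.92 FPKM without a call, and TMEM173 was the higher member. Of 29 measured interferon response genes 2 were higher and 1 lower (median -0.14, percentile 2.44). HERC5 (0.665 and 9.39 FPKM) and IFIT5 (2.63 and 7.15) were higher, and ISG15 was lower at 74.8 and 32.7 FPKM (43.8%). The interferon median was -0.49 (percentile 0.21) with FPKM of at least 5, was -0.01 (percentile 2.18) with no filter, and was within the random range with a pseudocount of 5 or with 10 expression bins. With no filter the sensing median was -0.35. Of 14 antigen presentation genes 3 were higher and 1 lower (median 0.21, percentile 72.9). HLA-C was at 23.9 and 71.3 FPKM, HLA-B at 9.88 and 22.4, ERAP2 at 0.072 and 1.67, and the immunoproteasome gene PSMB9 was lower at 2.92 and 0.462. Of 8 measured NF-kB genes 2 were higher (CSF1 and CCL2) and 1 lower (NFKBIA, 73.7 and 26.7 FPKM), with a median of -0.47 at percentile 0.68. With no filter on low values the NF-kB median was 0 at percentile 13.6, inside the marks. Under the other alternatives it ranged from -0.94 with FPKM of at least 5, over only 3 genes, to -0.16 with a pseudocount of 5. With a pseudocount of 5 the calls of IFIT5, HLA-B, ERAP2, PSMB9, CSF1 and CCL2 were lost. As in the paragraphs above, the epithelial median in this library was 38.6% of control.

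Known targets of the 2 microRNA families did not stand apart as lists. Of 23 measured miR-25 family targets 4 were higher and 0 lower (median -0.07, percentile 14.5). The higher genes were SMAD7 (4.31 and 21.8 FPKM), DSC2 (1.01 and 4.54), CDKN1C (0.278 and 2.21) and ITGA5 (2.70 and 7.50), of which all but SMAD7 lost the call with a pseudocount of 5. Of 30 miR-93 family targets 1 was higher (SMAD7) and 2 lower (NCOA3 and CCND1), with a median of -0.06 at percentile 16.5. Over the alternatives the miR-25 target median ranged from -0.16 with FPKM of at least 5 (percentile 7.14) to -0.02 with no filter. The miR-93 target median ranged from -0.13 with FPKM of at least 5 (percentile 10.8) to -0.01 after rescaling to the same 75th percentile. All of these were inside the marks. RNA of other cells in the sample, weighed at the end, could hide or add to a shift of these lists. They therefore cannot show whether the targets responded in MCF-7 cells. CCND1 (cyclin D1) was at 184 and 77.9 FPKM, 42.3% of control, and the autophagy kinase ULK1 at 39.4 and 19.4 FPKM without a call.

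Genes with a seed site differed little from genes without one. RNA of other cells in the sample, weighed at the end, could shift these medians, and the matching does not remove that. Over 12326 protein-coding genes, the median difference was 0.10 for the 1581 genes with a miR-25-3p site, 0.10 for the 3056 with a miR-93-5p site and 0.12 for the 8390 with neither. Genes with either site lay -0.02 from genes without (-0.06 with FPKM of at least 5 in at least 1 library). Random genes matched on expression and UTR length had a higher median, 0.16, with a range of 0.14 to 0.18, so the site genes were at percentile 0, -0.07 from the random median. Against other words of the same base composition, the miR-25-3p word ranked 32 of 630 from the lowest (5.08%) and the miR-93-5p word 21 of 420 (5%), just over and at the 5% mark. With UTRs matched by gene symbol alone, the first version run, the ranks were 41 of 630 (6.51%) and 23 of 420 (5.48%) and the percentile was 0. The 3' UTR of NCOA3 had 2 miR-93-5p sites and 0 miR-25-3p sites, that of TET2 had 1 miR-93-5p site, and those of MB21D1 (1518 bases) and TMEM173 (297 bases) had 0 of either.

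**Figure D3:**
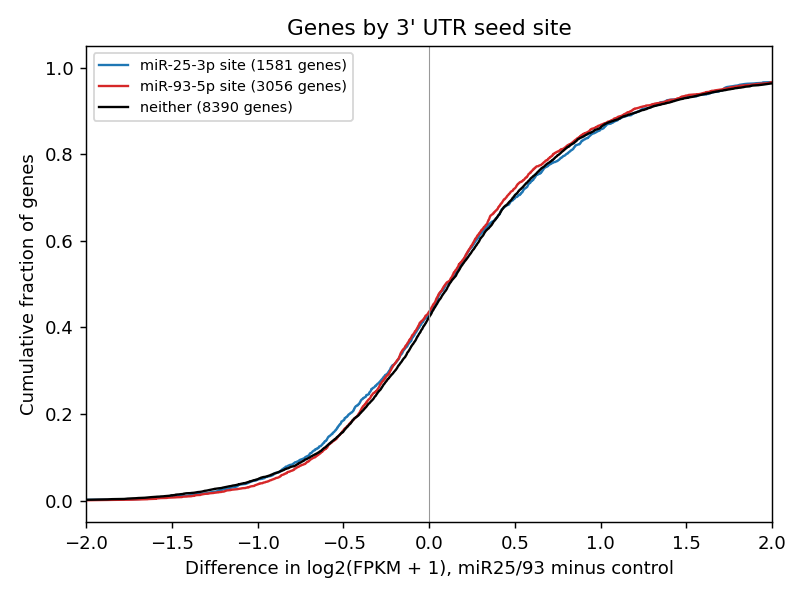
Cumulative fraction of genes (y axis) against the difference in log2(FPKM + 1), miR25/93 minus control (x axis, drawn from -2 to 2), for genes with a miR-25-3p site (1581), a miR-93-5p site (3056) or neither (8390). The 3 curves nearly overlap, with medians of 0.10, 0.10 and 0.12.

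The medians of unfolded protein response and immediate early genes lay above those of random lists, and that of cholesterol synthesis genes below. Of 22 unfolded protein and amino acid response genes 8 were higher and 2 lower (median 0.42, percentile 99.1). The serine synthesis gene PSAT1 was listed at 0 in the control and at 32.9 FPKM, PHGDH was at 9.38 and 45.8, ATF3 at 1.68 and 17.8 and PPP1R15A at 7.23 and 27.5. Of 15 immediate early genes 5 were higher and 1 lower (median 0.69, percentile 99.8), with DUSP1 at 4.45 and 49.0 FPKM, JUN at 12.6 and 56.3 and NR4A1 at 1.52 and 5.44. Both lists were within the random range with a pseudocount of 5, and the immediate early list also with FPKM of at least 5. Of 21 cholesterol synthesis genes 1 was lower (DHCR7, 125 and 61.3 FPKM) and 2 higher (STARD4, 1.40 and 7.01, and HMGCS1, 21.3 and 65.6), with a median of -0.56 at percentile 0.02. Of 25 hypoxia genes 4 were higher and 0 lower (median 0.24, percentile 89.2), namely the glucose transporter SLC2A3 (0.010 and 26.7 FPKM), NDRG1 (3.82 and 40.1), ADM (1.32 and 6.86) and ALDOC (3.29 and 9.26). Of 25 p53 targets 3 were higher and 0 lower (median 0.25, percentile 93.3), CCNG1 (33.2 and 105 FPKM), BBC3 (4.73 and 13.4) and ZMAT3 (2.496 and 6.68). Of 34 cell cycle genes 2 were higher, CDC6 and AURKB (median 0.06, percentile 90.8). The calls of STARD4, DHCR7, NR4A1, ADM, ALDOC, BBC3, ZMAT3, CDC6 and AURKB were lost with a pseudocount of 5, and that of DHCR7 also after rescaling to the same 75th percentile. The epithelial and amplicon medians of 38.6 and 39.9% of control apply beside these lists too.

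Among the remaining lists, histone genes lay below and ribosomal protein genes above random lists, and both stayed outside the marks under every alternative run, although the histone median was -0.27 with a pseudocount of 5 and -0.19 with no filter. In the same library the epithelial median was 38.6% of control and the amplicon median 39.9%. Of 14 genes linked to DNA and histone modification, the metabolic enzymes IDH1 and IDH2 included, 1 was higher (TET1) and 4 lower. The lower genes included TET2, IDH1 (44.6% of control) and IDH2 (43.5%), and the list median was 0.09 at percentile 64.9. Of 16 nuclear receptor coregulators 1 was higher (MED1, 7.44 and 19.7 FPKM) and 2 lower (NCOA3 and NRIP1), with a median of 0.20 at percentile 84.9. The 13 microRNA machinery genes (median 0.23, percentile 78.3), 30 oxidative phosphorylation genes (median -0.03, percentile 70.0), 11 histone genes (median -0.49, percentile 0.53) and 14 housekeeping genes (median -0.27, percentile 12.2) had 0 called genes. The oxidative phosphorylation median turned to 0.03 after rescaling to the same 75th percentile. Of 35 ribosomal protein genes 2 were higher, RPL23 (235 and 523 FPKM) and RPL19 (270.3 and 573), with a median of 0.18 at percentile 98.8. Of 15 immune cell genes 2 were measured, CD68 (1.62 and 8.05 FPKM) and CORO1A (20.7 and 12.5), and 0 of 9 endothelial genes were measured. The calls of MED1, NRIP1 and CD68 were lost with a pseudocount of 5.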

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

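Of 158 named genes under 4 alternatives each, 585 of 632 values kept their side of the 2-fold call, 30 no longer passed it, 17 newly passed it and 0 changed direction with a call. Among the 4, rescaling to the same median moved the library by only -0.004, so its values in this tally test almost nothing. Of 26 list medians, 171 of 181 values kept their side of the marks and 8 moved inside the marks. Both kinds of rescaling move the random lists along with each list, so they hardly test its place among them. Of the 171, 2 changed sign inside the marks. The DNA and histone modification list was at -0.06 with FPKM of at least 5. The oxidative phosphorylation list was at 0.03 after rescaling to the same 75th percentile. The remaining 2 values lost the marks and changed sign, the basal epithelial median, 0.0878 with FPKM of at least 5 and 0.0197 with no filter on low values, the first over 7 genes and the second over 17. The interferon median was -0.0562 with a pseudocount of 5 (percentile 4.54) and -0.135 with 10 bins (percentile 2.59), both inside the marks; the cause was not tested. The count of higher genes was 552 with a pseudocount of 5, 1019 with FPKM of at least 5 in at least 1 library, where 9901 genes were tested, and 836 with FPKM of at least 1 in both, where 12045 were tested. The count of lower genes was 1031 with a pseudocount of 0.1 and 262 with a pseudocount of 5, since the pseudocount sets how far low values count. On the log2(FPKM + 1) scale it was 8 when counted from the median of the epithelial list, an alternative chosen after seeing the data. Rescaling, summing rows and leaving out small RNA genes left both counts within 1.5 times of the reported ones. The seed site difference ranged from -0.06 to -0.02 over its alternatives, with percentiles from 0 to 0.04; with UTRs matched by symbol alone, added after the result had been seen, it was -0.02. No paired analysis was possible because each condition has 1 library and the labels give no replicate numbers. For the same reason no library could be left out. Depth limits genes with few reads: for a transcript of 1 kb, 1 read was worth 0.0376 FPKM in the control and 0.0345 in the miR25/93 library.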

Other observations

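The genes in this paragraph were picked after their values had been seen and were not tested as a group. The limb and trunk homeobox genes HOXD10, HOXD11 and HOXD13, neighbours at 2q31.1, were listed at 0 in the control and at 11.3, 14.1 and 11.6 FPKM. The fetal RNA-binding genes IGF2BP2 and IGF2BP3 were at 0.090 and 0.018 FPKM in the control and at 13.6 and 10.2, and HMGA2, a fetal chromatin protein gene, at 0.136 and 26.8. The neurofilament gene NEFL was listed at 0 and at 25.1 FPKM, and the testis and tumour antigen gene PRAME was at 0.017 and 14.6.

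Of the tests below, those of library scaling, of NCOA3 alone and both of MB21D1 alone were chosen only after the result had been seen. The NCOA3 test was first part of the amplicon test and was separated from it once its value was known, and the scaling test replaced one in which rescaling moved the library by only -0.004 and so tested nothing. The seed site test was planned, but its UTR matching was changed after its first result.

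The first pattern is that epithelial genes were lower and 42 near-silent genes were abundant in the miR25/93 library, with 0 in the reverse direction. Scaling is argued against, since 1 factor moves all genes alike: over members at 1 FPKM or more in both libraries, the median percent of control of 7 mesenchymal genes (247%, quartiles 131 and 390%) was 6.39 times that of 20 epithelial genes (38.6%, quartiles 35.3 and 49.2%). A change of expression within MCF-7 cells alone is argued against by MTAP, a gene of the segment that MCF-7 has lost, which was 15.7-fold higher. This rests on background knowledge of the line and on 1 gene that had not been looked at before. Its neighbour CDKN2A had been seen, so MTAP was not an independent choice. The control also held MTAP at 0.480 FPKM, an estimated 63 reads, and the source of these was not tested. A candidate explanation is RNA from cells other than MCF-7 in that sample, as MTAP was at 7.52 FPKM there. A change in the MCF-7 cells in addition to such RNA stays open.

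The source of such RNA was not identified. Of 7 embryonic kidney line markers 5 were measured, 3 of them higher and 1 lower (median 2.27, percentile 99.96). With no filter on low values the median over all 7 was 0.26, at percentile 89.4 and inside the marks, and with a pseudocount of 5 it was 1.34. LIN28B was listed at 0 in the control and at 7.70 FPKM, IGF2BP1 was at 0.153 and 18.6, and ZIC2 at 3.59 and 21.2. MEST, the most abundant of these markers in the control, was lower at 40.1 and 12.5 FPKM, HOXA10 was at 5.76 and 4.82, and NEFM (0.126) and PAX2 (0.201) were under 1 FPKM with miR25/93. The control itself held 3 of these markers at 1 FPKM or more. Of 7 fibroblast markers 0 were measured, and of 7 basal breast line markers 4 were, with 1 higher, MMP14, not called with a pseudocount of 5 (median 0.27, percentile 53.4).

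The second pattern is that NCOA3 and MB21D1 were lower with miR25/93. Dilution of MCF-7 transcripts by RNA of other cells may lower both: the amplicon list, whose values had not been seen, had a median difference of -1.22, and NCOA3, at 36.5% of control, lay within the 5th to 95th percentile of the epithelial list (29.02 to 78.2%). A moderate decrease of another cause would lie in this wide range too, so the place of NCOA3 in it cannot single out dilution. For MB21D1, at 26.3% of control, dilution and a further decrease cannot be told apart, because its counting interval of 22.7 to 30.4% spans the 5th percentile of the epithelial list. That interval covers counting error, not the spread between genes. MB21D1 itself lay below the lowest epithelial gene (ST14, 27.9%) and the lowest measured amplicon gene (TUBD1, 34.3%). The estrogen response genes AREG (14.1%) and PDZK1 (17.8%) lay lower still. The interval of MB21D1 lay below the 5th percentile of the amplicon list (34.6%) and above that of the estrogen response list (21.2%). The answer therefore depends on the list. Direct repression through 7-base seed sites is argued against for MB21D1, whose 2 annotated 3' UTRs held 0 such sites. They held 1 shorter match of 6 bases, which was not tested. Such repression stays open for NCOA3, which has 2 miR-93-5p sites and 0 miR-25-3p sites. Genes with a miR-93-5p site were at percentile 0 of matched random genes. RNA of other cells in the sample could shift site genes too, since the matching covered expression and UTR length only. This place among random genes therefore cannot decide for or against repression. The miR-93-5p word ranked 21 of 420 from the lowest (5%), at the 5% mark set for it. In the first version run it was over that mark (5.48%). The miR-25-3p word, at 5.08% as reported and 6.51% in the first version, does not bear on NCOA3. Since there is 1 library per condition, an effect of the microRNAs on NCOA3 and MB21D1 could be neither shown nor excluded beside the lower amplicon list (-1.22).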
